A study of Micropterus salmoides with 18 samples.

How the data were processed

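RNA sequencing libraries from gonads of largemouth bass (Micropterus salmoides, a freshwater fish of North American origin that is widely farmed) were analysed. Per the labels, 216 fish were placed in 12 tanks of 18, males and females apart. Control tanks stayed at 20 °C and heated tanks were brought to 28 °C within 2 h, with 3 tanks per group. Gonads taken at day 0 carry the prefix IC, those taken after 28 days at 20 °C the prefix NC, and those taken after 28 days at 28 °C the prefix HT. The letters F and M stand for female and male. The 18 libraries fell into 6 labelled groups of 3 (IC-F, IC-M, NC-F, NC-M, HT-F and HT-M), and each was built from 0.4 ug of total RNA, per the labels' protocols. No label says whether the 3 libraries of a group came from separate fish or tanks, so p-values measure the spread between these libraries, which may be technical.

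The deposited table gave FPKM (fragments per kilobase of gene, scaled by the mapped fragments) with 2 decimals for 43106 genes, per the file headers. The aligner, the counting tool and the genome build are not given in the sources used here. Of the table's entries, 5484 carried only an MSTRG number and 37622 a gene name, of which 34962 matched a symbol of the RefSeq gene table for assembly ASM1485139v1. That table served only for names and for the order of neighbouring genes, and no coordinates were taken from it. FPKM are not counts, so the depth of the libraries is unknown and no counting interval was computed. The FPKM of a library summed to between 745181 and 1020595. Some genes that every cell uses, such as the mitochondrial gene ND1, were listed at exactly 0 in whole groups, so an exact 0 can be a failed estimate. Where a library of a group was listed at 0, each library's value is given for that group, with no mean.

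Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) (lmFit, contrasts.fit and eBayes with trend), on genes with an FPKM of at least 1 in at least 3 of the libraries fitted. P-values were adjusted by the Benjamini-Hochberg method within each contrast and called under 0.05. Fold changes are differences on the log2(FPKM + 1) scale, which understates the change of low genes, and levels are given as mean ± SD of FPKM over 3 libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

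Before the data were examined, 8 contrasts were fixed: HT against NC, NC against IC and HT against IC within each letter (9 libraries in each fit), the difference of the heat effects between the letters, and IC-F against IC-M (18 libraries in each fit). The gonad genes then went against the letters in 12 of the 18 libraries, as the report describes. The planned contrasts were kept as written, and groups are named as "the libraries labelled" HT-F and so on. A further 7 contrasts, chosen only after the gonad genes were seen, compared labelled groups with the same kind of gonad genes: HT-M with NC-F, NC-F with IC-M and HT-M with IC-M (a fit of these 9 libraries), HT-F with NC-M, NC-M with IC-F and HT-F with IC-F (a fit of the other 9), and the difference of the 2 heat effects (18 libraries). The prefixes were taken from the labels, which do not say which letters are wrong or whether any prefix is.

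A total of 34 gene lists was fixed before the data were examined: heat shock proteins, cold-inducible RNA-binding proteins, unfolded protein response, steroidogenesis, gonadotropin and sex steroid receptors, cholesterol synthesis, oocyte, granulosa and theca cells, Sertoli and Leydig cells, spermatogonia, meiosis, sperm and flagellum, cell cycle, p53 response, antioxidant and glutathione, oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins, proteasome and ubiquitin, fatty acid and lipid metabolism, myeloid cells, lymphocytes, interferon response, complement and acute phase, extracellular matrix, endothelium, red blood cells, liver and yolk precursors, skeletal muscle, DNA methylation and chromatin, circadian clock, corticosteroid-responsive genes, hypoxia response, and gonadal sex determination. Lists with at least 5 tested genes were compared with all other genes by camera with a preset correlation of 0.01, and again with an estimated correlation. With the estimated correlation, the only list calls that held were those of the oocyte list in HT-M against NC-M (adjusted p = 0.0257) and in NC-M against IC-M (adjusted p = 0.0241).

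Named genes followed a rule fixed before the data were examined. For each heat contrast, it took the 10 largest rises and 10 largest falls among genes with a symbol, adjusted p under 0.05, an absolute log2 change of at least 1, libraries that did not overlap and a mean of at least 5 FPKM in the higher group. It also took up to 3 called members of each list with the smallest adjusted p, or the member with the smallest p where none was called. For the other contrasts it took the 5 largest rises and 5 largest falls, without the overlap condition for the differences of effects. The contrasts chosen later followed the same rule. The list members were taken in the heat contrasts of like gonads in place of the planned ones, where they would show gonad type. The text names part of the genes that the rule took. The mitochondrial protein genes were also counted as a set, which was no list fixed in advance.

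Alternatives were a pseudocount of 0.1, no filter and a filter at 5 FPKM, median-of-ratios scaling, rescaling each library's FPKM to a common sum, an added log2 threshold of 1, a replicate block, other sets of libraries in the fit, each library left out in turn, and, chosen after the data were seen, the fits without the libraries NC-M 1 and NC-M 2, which leave 1 NC-M library and take the spread from the other groups.

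The fitting steps were tested on simulated data, in which 200 genes were changed, 100 of them by 1 and 100 by 2 on the log2 scale. Of the genes changed by 1 and by 2, 65 and 86 were called for HT-F against NC-F (22899 genes), 19 and 73 for HT-M against NC-M (21463 genes), 53 and 88 for IC-F against IC-M (25184 genes), 56 and 89 for HT-M against NC-F (17026 genes), 13 and 69 for HT-F against NC-M (22791 genes), and 18 and 62 for the difference between the last 2 effects (25184 genes). Unchanged genes made up between 3.59% and 8.89% of the calls. Small changes in the NC-M contrasts were thus mostly missed in the simulation. The data had far more called genes than the 200 changed here (15709 for HT-M against NC-M). The adjusted threshold depends on that number, so these shares need not hold for the data.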

Results

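Gonad transcriptomes of largemouth bass were compared at day 0 (IC) and after 28 days at 20 °C (NC) or at 28 °C (HT) in 18 libraries that formed 6 labelled groups of 3. Each library had between 15152 and 21638 genes at 1 FPKM or more. The correlation of log2 values across genes lay between 0.958 and 0.991 within 5 of the groups and between 0.903 and 0.945 within NC-M. Depth is unknown, since only FPKM were used.

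The gonad genes did not follow the letters. Libraries are called ovary-type below where the genes of the preset oocyte list (egg coat and maternal-effect genes) were high and those of the sperm and flagellum list low, and testis-type in the opposite case. The median oocyte gene stood at 6.88 to 7.24 on the log2(FPKM + 1) scale in the 9 libraries labelled IC-M, NC-F and HT-M, and at 1.24 to 1.82 in the 9 labelled IC-F, NC-M and HT-F. The median sperm gene stood at 0.32 to 0.61 in the first set and at 3.46 to 5.91 in the second. All 6 IC and all 6 HT libraries thus went against their letter, and the 6 NC libraries followed it. Libraries of unlike type correlated at 0.656 to 0.742. Every direction below refers to the libraries as labelled.

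**Figure D1:**
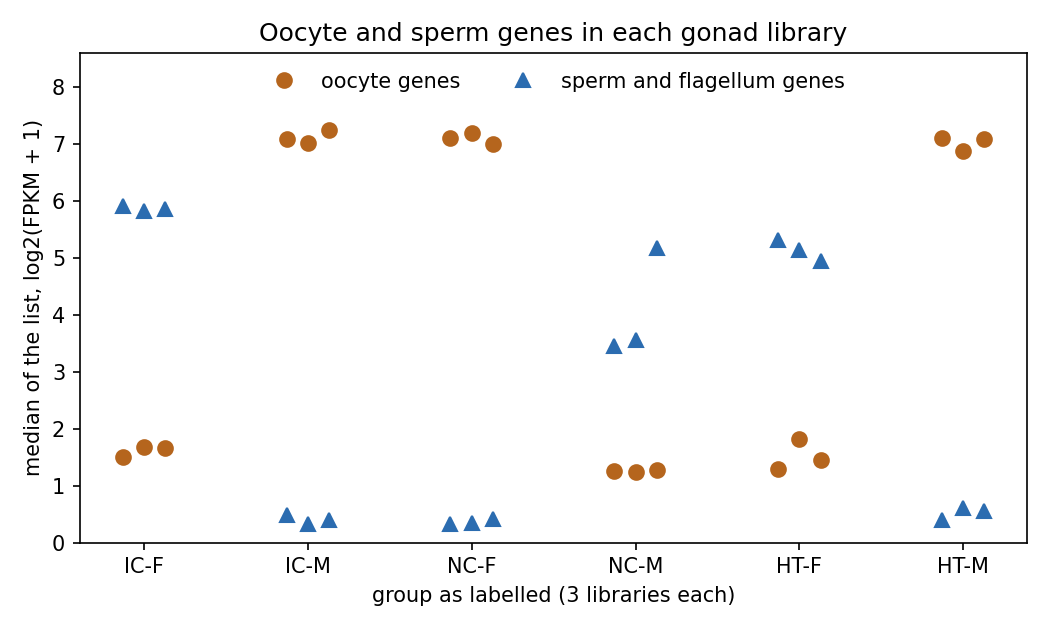
Median of the oocyte list (circles) and of the sperm and flagellum list (triangles) in each of the 18 libraries, on the log2(FPKM + 1) scale, by labelled group. Oocyte genes were high in IC-M, NC-F and HT-M, and sperm genes in IC-F, NC-M and HT-F, where the libraries NC-M 1 and NC-M 2 lay at 3.46 and 3.56 and NC-M 3 at 5.18.

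Gonads of the letters F and M were compared at day 0. The libraries labelled IC-F held the transcripts of a testis. The sperm tail gene odf3b (outer dense fibre) stood at 1403 ± 16.4 in IC-F against 0 in all 3 libraries labelled IC-M, and the radial spoke gene rsph14 of the sperm flagellum at 676 ± 39.5 in IC-F against 0.19, 0.12 and 0 in the 3 libraries labelled IC-M. The testis transcription factor gene dmrt1 reached 45.0 ± 2.89 in IC-F against 0.05 ± 0.01 in IC-M (log2 5.45 ± 0.119 SE, limma adjusted p = 1.11e-14). The Leydig cell hormone gene insl3 reached 40.4 ± 4.62 in IC-F against 0, 0.1 and 0.21 in the 3 libraries labelled IC-M. The meiotic gene hormad1 reached 288 ± 14.0 in IC-F against 1.69 ± 0.401 in IC-M. The libraries labelled IC-M held those of an ovary. The egg coat gene zpd stood at 302 ± 17.0 in IC-M against 2.21 ± 0.218 in IC-F (log2 −6.56 ± 0.152 SE, limma adjusted p = 1.91e-14), and the maternal-effect gene zar1l at 779 ± 32.3 in IC-M against 0.287 ± 0.297 in IC-F. Btg4, which clears maternal mRNA, stood at 717 ± 66.2 in IC-M against 0.43 ± 0.0755 in IC-F, and the oestrogen-synthesis gene hsd17b1 at 23.8 ± 2.20 in IC-M against 0.153 ± 0.0666 in IC-F. The ovarian transcription factor gene foxl2a stood at 11.3 ± 0.952 in IC-M and at 0.03, 0 and 0.12 in the 3 libraries labelled IC-F. Of 25184 genes, 12412 were higher in IC-F and 7208 higher in IC-M.

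The planned heat contrasts within a letter set unlike gonads against each other. In HT-F against NC-F, the flagellar gene cfap73 stood at 482 ± 63.0 in HT-F against 0.113 ± 0.0709 in NC-F and the maternal-effect gene zar1 at 2.74 ± 1.06 in HT-F against 1118 ± 79.4 in NC-F. Of the 17 oocyte genes, 1 rose and 16 fell (1 and 16 adjusted over the list alone). The median oocyte gene changed by log2 −5.14 (camera adjusted p = 3.98e-09, and adjusted p = 0.533 with an estimated correlation). Of the 66 sperm and flagellum genes, 63 rose and 1 fell (63 and 1 adjusted over the list alone). The median sperm and flagellum gene changed by log2 4.19 (camera adjusted p = 6.64e-12, and adjusted p = 0.766 with an estimated correlation). The unfolded protein response and antioxidant lists fell and the meiosis list rose (camera adjusted p = 0.0365, 0.0365 and 0.00341, each with adjusted p = 0.766 with an estimated correlation). In all, 12504 genes were higher and 6501 lower of 22899. After median-of-ratios scaling, 55.2% of the called genes were higher, against 65.8%, and 12 lists were called instead of 5. Without HT-F 1, NC-F 2 or NC-F 3, 10, 10 and 8 lists were called, and without HT-F 2, which ends the unfolded protein response and antioxidant calls, 3 lists.

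HT-M against NC-M ran the other way: the autophagy-related gene map1lc3c stood at 1456 ± 248 in HT-M against 0.903 ± 0.361 in NC-M. Of the 17 oocyte genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone). For the oocyte list the median was log2 5.16 (camera adjusted p = 6.9e-09, and adjusted p = 0.0257 with an estimated correlation). Of the 63 sperm and flagellum genes, 2 rose and 56 fell (2 and 56 adjusted over the list alone). For the sperm and flagellum list the median was log2 −3.31 (camera adjusted p = 1.45e-08, and adjusted p = 0.916 with an estimated correlation). In this contrast the cell cycle and unfolded protein response lists also rose, and the Sertoli and Leydig, meiosis, ribosomal and interferon lists fell (camera adjusted p between 0.00131 and 0.0261, and adjusted p between 0.706 and 0.916 with an estimated correlation). The cell cycle call ended without NC-M 1 or NC-M 2, and the unfolded protein response call without any 1 of the NC-M libraries. In all, 6662 genes were higher and 9047 lower of 21463, and 10354 in place of 15709 were called with a filter at 5 FPKM. The majority turned with that filter (5517 higher and 4837 lower) and without NC-M 1, NC-M 2 or NC-M 3 (6273 and 5189, 6230 and 4842, and 7140 and 5379).

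The planned contrasts of 28 days at 20 °C also crossed gonad types. In NC-F against IC-F, 7282 genes were higher and 12182 lower. Of the 17 oocyte genes, 16 rose and 1 fell (16 and 1 adjusted over the list alone). The median oocyte gene changed by log2 5.45 (camera adjusted p = 1.09e-07, and adjusted p = 0.379 with an estimated correlation). Of the 66 sperm and flagellum genes, 1 rose and 64 fell (1 and 64 adjusted over the list alone). The median sperm and flagellum gene changed by log2 −4.94 (camera adjusted p = 3.79e-13, and adjusted p = 0.409 with an estimated correlation). The antioxidant, oxidative phosphorylation, cell cycle and ribosomal lists rose and the meiosis list fell in the same contrast (camera adjusted p between 0.000101 and 0.038, and adjusted p between 0.379 and 0.918 with an estimated correlation). The ribosomal call ended without IC-F 1 or IC-F 3. In NC-M against IC-M, 9578 genes were higher and 6439 lower. Of the 17 oocyte genes, 1 rose and 15 fell (1 and 16 adjusted over the list alone). For the oocyte list the median was log2 −5.24 (camera adjusted p = 4.23e-09, and adjusted p = 0.0241 with an estimated correlation). Of the 63 sperm and flagellum genes, 54 rose and 2 fell (54 and 2 adjusted over the list alone). For the sperm and flagellum list the median was log2 3.44 (camera adjusted p = 1.12e-07, and adjusted p = 0.938 with an estimated correlation). The Sertoli and Leydig, ribosomal, interferon, extracellular matrix, endothelium and skeletal muscle lists rose and the unfolded protein response and cell cycle lists fell in it (camera adjusted p between 0.000168 and 0.0405, and adjusted p between 0.864 and 0.938 with an estimated correlation). The skeletal muscle and unfolded protein response calls ended without any 1 of the NC-M libraries, the cell cycle call without NC-M 1, and the extracellular matrix call without IC-M 1. With a filter at 5 FPKM, 10496 genes were called in NC-M against IC-M in place of 16017. The majority turned with that filter (5045 higher and 5451 lower) and without NC-M 1, NC-M 2 or NC-M 3 (5678 and 6023, 5405 and 6049, and 5903 and 6911). The difference between the planned heat effects of the letters was called for 21143 of 25184 genes.

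The planned contrasts of heat against day 0 compared like gonads. In the testis-type pair, HT-F against IC-F, the genes igfbp1a, g0s2 and tgm8 were among the largest rises. Igfbp1a, which binds insulin-like growth factors, reached 11.4, 68.7 and 69.8 in the 3 libraries labelled HT-F against 2.18 ± 0.476 in IC-F (log2 3.64 ± 0.589 SE, limma adjusted p = 0.00109). G0s2, an inhibitor of fat breakdown, reached 66.2 ± 41.4 in HT-F against 3.30 ± 0.854 in IC-F (log2 3.75 ± 0.447 SE, limma adjusted p = 0.000215). The transglutaminase gene tgm8 stood at 135 ± 36.4 in HT-F against 3.21 ± 0.987 in IC-F (log2 5.01 ± 0.354 SE, limma adjusted p = 1.53e-05), and a similar level of 158 ± 40.9 in NC-M was measured without heating. The respiratory chain gene COX2 of the mitochondrial genome fell to 1190.3 ± 331 from 21496 ± 2975 (log2 −4.21 ± 0.197 SE, limma adjusted p = 2.61e-06), ND3 to 111 ± 13.5 from 1298 ± 179. Palm1a, a membrane-associated gene, fell to 4.33 ± 1.27 in HT-F from 149 ± 7.47 (and 5.93 ± 4.01 in NC-M). The kinase gene jak3 stood at 0.433 ± 0.0764 in HT-F against 18.1 ± 4.12 in IC-F. Zgc_114181 stood at 524 ± 478 in HT-F against 3.41 ± 0.455 in IC-F and mettl3 at 11.5 ± 6.04 in HT-F against 0 in all 3 libraries labelled IC-F. ND1 was listed at 0 in all 3 libraries labelled HT-F against 321 ± 97.4 in IC-F. In all, 6736 genes were higher and 5177 lower of 22899, and 5438 in place of 11913 were called when the fit held testis-type libraries only. After median-of-ratios scaling, 44.8% of the called genes were higher, against 56.5%, and with a log2 threshold of 1, 1756 were higher and 2140 lower.

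In the fit of testis-type libraries, chosen later, several preset lists differed between HT-F and IC-F. Of the 66 sperm and flagellum genes, 1 rose and 12 fell (1 and 10 adjusted over the list alone). The median sperm and flagellum gene changed by log2 −0.77 (camera adjusted p = 4.66e-07, and adjusted p = 0.762 with an estimated correlation). Of the 44 antioxidant and glutathione genes, 22 rose and 0 fell (24 and 1 adjusted over the list alone). The median antioxidant and glutathione gene changed by log2 0.59 (camera adjusted p = 5.21e-06, and adjusted p = 0.251 with an estimated correlation). Of the 54 nuclear oxidative phosphorylation genes, 28 rose and 0 fell (32 and 0 adjusted over the list alone). The median nuclear oxidative phosphorylation gene changed by log2 0.66 (camera adjusted p = 1.08e-06, and adjusted p = 0.615 with an estimated correlation). Of the 26 glycolysis genes, 14 rose and 3 fell (16 and 3 adjusted over the list alone). The median glycolysis gene changed by log2 0.75 (camera adjusted p = 0.00683, and adjusted p = 0.615 with an estimated correlation). Of the 52 proteasome and ubiquitin genes, 16 rose and 0 fell (19 and 1 adjusted over the list alone). The median proteasome and ubiquitin gene changed by log2 0.53 (camera adjusted p = 0.00142, and adjusted p = 0.766 with an estimated correlation). Of the 52 fatty acid and lipid metabolism genes, 15 rose and 1 fell (18 and 2 adjusted over the list alone). The median fatty acid and lipid metabolism gene changed by log2 0.44 (camera adjusted p = 0.00142, and adjusted p = 0.615 with an estimated correlation). Of the 49 extracellular matrix genes, 14 rose and 0 fell (20 and 2 adjusted over the list alone). The median extracellular matrix gene changed by log2 0.54 (camera adjusted p = 0.00142, and adjusted p = 0.705 with an estimated correlation). Of the 15 corticosteroid-responsive genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone). Camera placed the corticosteroid-responsive list higher (camera adjusted p = 0.0254, and adjusted p = 0.615 with an estimated correlation). Of the 24 hypoxia response genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone). The median hypoxia response gene changed by log2 0.59 (camera adjusted p = 0.00632, and adjusted p = 0.615 with an estimated correlation).

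In the ovary-type pair, HT-M against IC-M, lhcgr, the luteinising hormone receptor gene, reached 43.8 ± 7.79 in HT-M against 0.297 ± 0.155 in IC-M (log2 5.10 ± 0.309 SE, limma adjusted p = 3.68e-05). An unnamed entry of the table had the complementary values, at 31.6 to 82.9 in the libraries with lhcgr at 1 FPKM or less and at 0 in HT-M. The same entry mirrored hspb9 and igfbp1a in ovary-type libraries, and other unnamed entries mirrored srp9 and zgc_109986. Of 21 named genes that were high in at least 3 and near 0 in at least 3 libraries of a gonad type, 20 had such an entry in either type. Another entry matched ND1, mettl3, rhbdd1 and myl2b alike, so a match can reflect a shared group pattern. Of all 256 such genes under a stricter rule, 39.8% had one, against 9.36% with shuffled libraries. Their levels may depend on how reads were assigned, which stays open. Ddit4, an inhibitor of the growth kinase mTOR, reached 40.0 ± 4.92 in HT-M against 1.05 ± 0.561 in IC-M (log2 4.35 ± 0.491 SE, limma adjusted p = 0.000973). Cunh18orf21 reached 46.0 ± 5.11 in HT-M against 3.23 ± 0.49 in IC-M. The small heat shock protein gene hspb9 stood at 13.9 ± 6.97 in HT-M against 0, 0.06 and 0 in the 3 libraries labelled IC-M. Zgc_109986 stood at 24.7 ± 2.01 in HT-M against 0, 0 and 0.07 in the 3 libraries labelled IC-M. On the lower side, mrps15, a mitochondrial ribosomal gene, stood at 0.893 ± 0.86 in HT-M against 96.2 ± 10.8 in IC-M. Srp9 stood at 0.417 ± 0.221 in HT-M against 21.2 ± 4.36 in IC-M, mettl3 at 0, 0 and 0.46 in the 3 libraries labelled HT-M against 36.8 ± 6.39 in IC-M. Si_ch211-140b10.6 stood at 1.42, 0 and 0 in the 3 libraries labelled HT-M against 42.1 ± 5.46 in IC-M. ND1 was listed at 0 in all 3 libraries labelled HT-M against 506 ± 20.0 in IC-M. In all, 1240 genes were higher and 516 lower of 21463. The count of 1756 rose to 4179 when the fit held ovary-type libraries only, and fell to 1012, 922, 816, 805 and 868 without HT-M 1, HT-M 2, HT-M 3, IC-M 1 and IC-M 2. ND1 and srp9 lost their calls without any 1 of the 6 libraries. After median-of-ratios scaling, 58.3% of the called genes were higher, against 70.6%.

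In the fit of ovary-type libraries, several lists of somatic cell types were higher in HT-M than in IC-M. Of the 15 granulosa and theca genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone). The median granulosa and theca gene changed by log2 0.83 (camera adjusted p = 3.43e-05, and adjusted p = 0.209 with an estimated correlation). Of the 10 myeloid cell genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone). The median myeloid cell gene changed by log2 1.25 (camera adjusted p = 0.000553, and adjusted p = 0.209 with an estimated correlation). Of the 14 endothelial genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone). The median endothelial gene changed by log2 1.35 (camera adjusted p = 2.41e-05, and adjusted p = 0.261 with an estimated correlation). Of the 39 extracellular matrix genes, 23 rose and 1 fell (26 and 1 adjusted over the list alone). For the extracellular matrix list the median was log2 0.79 (camera adjusted p = 2.85e-07, and adjusted p = 0.261 with an estimated correlation). Of the 13 corticosteroid-responsive genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone). For the corticosteroid-responsive list the median was log2 0.84 (camera adjusted p = 0.00104, and adjusted p = 0.261 with an estimated correlation). Of the 13 Sertoli and Leydig cell genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone). The median Sertoli and Leydig cell gene changed by log2 0.81 (camera adjusted p = 0.0191, and adjusted p = 0.261 with an estimated correlation). Of the 21 sex determination genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone). The median sex determination gene changed by log2 0.55 (camera adjusted p = 0.0181, and adjusted p = 0.283 with an estimated correlation). The call of the Sertoli and Leydig list ended without HT-M 1, HT-M 2, HT-M 3 or IC-M 3, and that of the sex determination list without IC-M 3. Of the 78 cell cycle genes, 2 rose and 6 fell (2 and 5 adjusted over the list alone). The median cell cycle gene changed by log2 −0.08 (camera adjusted p = 0.00927, and adjusted p = 0.408 with an estimated correlation). The cell cycle median turned to 0.01 with each library rescaled to a common sum. The skeletal muscle list had a median of log2 2.32 (5 of 7 rose) and the red blood cell list one of 0.78 (4 of 8 rose), but neither was called (camera adjusted p = 0.105 and 0.242, and adjusted p = 0.586 and 0.408 with an estimated correlation). Beside these, 5 of 16 oocyte genes fell and 0 rose.

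The libraries labelled HT-M and NC-F, both ovary-type and both from day 28, were compared after the gonad genes had been seen. Hormone receptor genes of the follicle were among the called genes, although their list was not called (camera adjusted p = 0.11, and adjusted p = 0.43 with an estimated correlation). Lhcgr, which an unnamed entry of the table mirrored, reached 43.8 ± 7.79 in HT-M against 1.30 ± 0.462 in NC-F (log2 4.29 ± 0.195 SE, limma adjusted p = 1.71e-06). Pgr, the nuclear progesterone receptor gene, reached 19.9 ± 4.59 in HT-M against 6.08 ± 0.942 in NC-F (log2 1.55 ± 0.196 SE, limma adjusted p = 0.000554). Fshr, the follicle-stimulating hormone receptor gene, reached 12.5 ± 0.191 in HT-M against 5.29 ± 0.142 in NC-F (limma adjusted p = 0.000763). Inhbaa, an activin subunit gene, stood at 1.93 ± 0.279 in HT-M against 0.0767 ± 0.0252 in NC-F. Star, which moves cholesterol into mitochondria for steroid synthesis, stood at 1.97 ± 0.232 in HT-M against 0.593 ± 0.204 in NC-F. The steroid dehydrogenase gene hsd20b2 fell to 0.253 ± 0.0586 in HT-M from 2.65 ± 0.6 in NC-F. Of the 15 granulosa and theca cell genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was log2 0.68 (camera adjusted p = 0.00125, and 0.43 with an estimated correlation). Of the 16 oocyte genes, 3 rose and 8 fell (3 and 8 adjusted over the list alone). Their median was log2 −0.31 (camera adjusted p = 0.063, and 0.43 with an estimated correlation). Among these, zar1 fell to 514 ± 4.67 in HT-M from 1118 ± 79.4 in NC-F (log2 −1.12 ± 0.145 SE, limma adjusted p = 0.000622). The egg coat genes fell too, zpax1 to 240.0 ± 11.1 in HT-M from 513 ± 31.6 in NC-F and zpd to 211 ± 7.85 in HT-M from 376 ± 26.1 in NC-F. Gdf9, an oocyte growth factor gene, fell to 43.7 ± 2.30 in HT-M from 68.8 ± 7.14 in NC-F.

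Genes of stroma and vessels rose in the same comparison. Of the 39 extracellular matrix genes, 30 rose and 1 fell (30 and 2 adjusted over the list alone). Their median was log2 0.69 (camera adjusted p = 6.25e-05, and 0.444 with an estimated correlation). Decorin (dcn) reached 9.91 ± 0.881 in HT-M against 1.58 ± 0.739 in NC-F (log2 2.12 ± 0.21 SE, limma adjusted p = 0.000172), and the laminin gene lamb1a 6.21 ± 0.761 in HT-M against 1.53 ± 0.113 in NC-F. Of the 14 endothelial genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone). Their median was log2 1.03 (camera adjusted p = 0.00905, and 0.561 with an estimated correlation). The vessel genes plvapb and kdrl (a VEGF receptor) stood at 9.05 ± 0.92 in HT-M against 2.08 ± 0.291 in NC-F and at 7.27 ± 1.90 in HT-M against 1.58 ± 0.376 in NC-F. The haemoglobin gene hbae5 reached 270.1 ± 15.3 in HT-M against 47.1 ± 35.5 in NC-F. The muscle genes tpm1 and tpm2 reached 46.6 ± 14.3 in HT-M against 12.7 ± 4.19 in NC-F and 38.1 ± 19.1 in HT-M against 5.60 ± 4.40 in NC-F. Csf1rb, a receptor gene of the macrophage lineage, reached 87.9 ± 17.5 in HT-M against 30.3 ± 5.29 in NC-F. Apoc1, an apolipoprotein gene, reached 9.30 ± 1.37 in HT-M against 0.203 ± 0.0757 in NC-F (log2 3.09 ± 0.204 SE, limma adjusted p = 1.85e-05).

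Corticosteroid-responsive genes rose as well. Of the 13 corticosteroid-responsive genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone). Their median was log2 0.55 (camera adjusted p = 0.00541, and 0.43 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, reached 17.4 ± 1.76 in HT-M against 4.14 ± 0.302 in NC-F (log2 1.83 ± 0.135 SE, limma adjusted p = 3.21e-05). Ddit4 reached 40.0 ± 4.92 in HT-M against 13.3 ± 1.09 in NC-F (log2 1.52 ± 0.187 SE, limma adjusted p = 0.000501). Dusp1, a phosphatase of MAP kinases, reached 29.9 ± 7.08 in HT-M against 11.7 ± 0.468 in NC-F (log2 1.25 ± 0.168 SE, limma adjusted p = 0.000727). Outside that list, igfbp1a, a member of the hypoxia list and mirrored by the same unnamed entry as lhcgr, stood at 16.4 ± 2.06 in HT-M against 3.59 ± 0.579 in NC-F (log2 1.93 ± 0.138 SE, limma adjusted p = 2.75e-05). The glycolysis regulator pfkfb3 stood at 58.2 ± 10.0 in HT-M against 21.4 ± 3.20 in NC-F. Of the 53 chromatin and DNA methylation genes, 31 rose and 5 fell (32 and 5 adjusted over the list alone). The median chromatin and DNA methylation gene changed by log2 0.42 (camera adjusted p = 0.0043, and adjusted p = 0.43 with an estimated correlation). That list was not called in HT-M against IC-M (median log2 0.05). The DNA methyltransferase gene dnmt1 reached 118 ± 9.35 in HT-M against 63.0 ± 4.13 in NC-F, and the demethylase gene kdm5a 10.6 ± 0.345 in HT-M against 5.60 ± 0.306 in NC-F.

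The ribosomal, proteasome, antioxidant and nuclear oxidative phosphorylation lists fell between NC-F and HT-M. Of the 87 cytosolic ribosomal protein genes, 6 rose and 37 fell (6 and 37 adjusted over the list alone). Their median was log2 −0.20 (camera adjusted p = 0.000426, and 0.451 with an estimated correlation). Rpl11 fell to 1847 ± 74.8 in HT-M from 3789 ± 77.0 in NC-F (log2 −1.04 ± 0.0707 SE, limma adjusted p = 2.11e-05). Of the 50 proteasome and ubiquitin genes, 7 rose and 24 fell (10 and 28 adjusted over the list alone). Their median was log2 −0.42 (camera adjusted p = 0.00105, and 0.655 with an estimated correlation). Of the 41 antioxidant and glutathione genes, 2 rose and 19 fell (2 and 19 adjusted over the list alone). Their median was log2 −0.35 (camera adjusted p = 0.00105, and 0.655 with an estimated correlation). Gpx1a, a glutathione peroxidase gene, fell to 88.6 ± 6.87 in HT-M from 216 ± 10.0 in NC-F (log2 −1.28 ± 0.111 SE, limma adjusted p = 8.29e-05). Of the 53 nuclear oxidative phosphorylation genes, 7 rose and 26 fell (8 and 26 adjusted over the list alone). Their median was log2 −0.23 (camera adjusted p = 0.00408, and 0.444 with an estimated correlation). The ATP synthase gene atp5f1c fell to 387 ± 14.9 in HT-M from 669.5 ± 13.1 in NC-F. Of 12 protein genes of the mitochondrial genome other than ND1, 7 rose and 0 fell, and 4 rose without NC-F 3. Against IC-M, 0 of these genes rose in HT-M and 8 fell.

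The heat shock list did not move in a common direction. Of the 38 heat shock protein and co-chaperone genes, 13 rose and 12 fell (14 and 12 adjusted over the list alone). The median heat shock protein and co-chaperone gene changed by log2 0.03 (camera adjusted p = 0.95, and adjusted p = 0.953 with an estimated correlation). Its median turned from 0.03 to −0.02 after median-of-ratios scaling. Hspb9 rose to 13.9 ± 6.97 in HT-M from 1.87 ± 0.834 in NC-F and hspa9, the mitochondrial Hsp70 gene, to 88.2 ± 6.83 in HT-M from 48.4 ± 9.12 in NC-F. The co-chaperone gene stip1 fell to 54.4 ± 3.14 in HT-M from 76.6 ± 3.78 in NC-F. Cirbpb, named for its induction by cold, was higher in the libraries labelled as 28 °C, at 962 ± 6.05 in HT-M against 624 ± 25.7 in NC-F (log2 0.62 ± 0.0714 SE, limma adjusted p = 0.000351). The stress transcription factor gene xbp1 fell to 13.0 ± 2.16 in HT-M from 52.0 ± 14.6 in NC-F. The meiotic gene mnd1 fell to 6.82 ± 1.33 in HT-M from 28.6 ± 2.97 in NC-F, and sycp3 to 0.86 ± 0.75 in HT-M from 7.11 ± 1.26 in NC-F.

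Many of the largest changes between NC-F and HT-M were of genes listed near 0 in whole groups, values that can be failed estimates. Birc5b, a cell division gene, stood at 1625 ± 194 in HT-M against 2.61 ± 0.946 in NC-F (and 1145 ± 205 in IC-M). Rab11fip5a stood at 37.1 ± 0.878 in HT-M against 1.42 ± 0.105 in NC-F, and tmprss2 at 17.0 ± 1.61 in HT-M against 0.0733 ± 0.0503 in NC-F. Wdr1 stood at 24.9 ± 0.912 in HT-M against 0.893 ± 0.356 in NC-F, and nudt2 at 52.5 ± 13.7 in HT-M against 0.27, 0.05 and 0 in the 3 libraries labelled NC-F. Mrm3a stood at 16.4 ± 0.797 in HT-M against 0.47, 0 and 0.2 in the 3 libraries labelled NC-F, and tmem41aa at 25.8 ± 6.93 in HT-M against 0 in all 3 libraries labelled NC-F. In the other direction, mrps15 stood at 0.893 ± 0.86 in HT-M against 115 ± 4.03 in NC-F, and fgf2 at 0.717 ± 0.124 in HT-M against 19.6 ± 1.66 in NC-F. Nek10 stood at 0.643 ± 0.0987 in HT-M against 17.2 ± 2.91 in NC-F, and arhgap39 at 0.483 ± 0.336 in HT-M against 25.2 ± 1.69 in NC-F. Rhbdd1 stood at 0, 0 and 0.09 in the 3 libraries labelled HT-M against 16.3 ± 0.162 in NC-F, and myl2b at 0, 0.08 and 0.08 in the 3 libraries labelled HT-M against 14.2 ± 1.37 in NC-F. Mettl3 stood at 0, 0 and 0.46 in the 3 libraries labelled HT-M against 21.2 ± 4.72 in NC-F. ND1 was listed at 0 in all 3 libraries labelled HT-M against 177 ± 8.96 in NC-F.

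Over all 17026 genes tested in HT-M against NC-F, 4886 rose and 3413 fell. The lists not called, with the counts that rose and fell over all genes and then adjusted over the list alone, were cold-inducible RNA-binding proteins (1 and 1 of 4, then 1 and 1), unfolded protein response (10 and 11 of 38, then 10 and 11), steroidogenesis (3 and 6 of 14, then 3 and 6), gonadotropin and sex steroid receptors (6 and 1 of 13, then 6 and 1), cholesterol synthesis (6 and 4 of 16, then 6 and 5), Sertoli and Leydig cells (5 and 1 of 13, then 5 and 1), spermatogonia (9 and 8 of 28, then 9 and 8), meiosis (2 and 7 of 20, then 2 and 7), sperm and flagellum (8 and 6 of 28, then 8 and 6), cell cycle (17 and 19 of 78, then 17 and 19), p53 response (10 and 6 of 32, then 10 and 6), glycolysis (5 and 8 of 21, then 5 and 8). The others were fatty acid and lipid metabolism (15 and 9 of 52, then 15 and 9), myeloid cells (5 and 2 of 10, then 5 and 2), lymphocytes (4 and 0 of 4, then 4 and 0), interferon response (5 and 2 of 18, then 5 and 2), complement and acute phase (1 and 0 of 5, then 1 and 0), red blood cells (4 and 2 of 8, then 4 and 3), liver and yolk precursors (2 and 0 of 4, then 2 and 0), skeletal muscle (5 and 0 of 7, then 5 and 0), circadian clock (5 and 2 of 23, then 5 and 2), hypoxia response (7 and 6 of 22, then 7 and 6) and gonadal sex determination (9 and 2 of 21, then 9 and 2). The share of called genes that rose moved from 58.9% to 71.5% when each library was rescaled to a common sum.

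**Figure D2:**
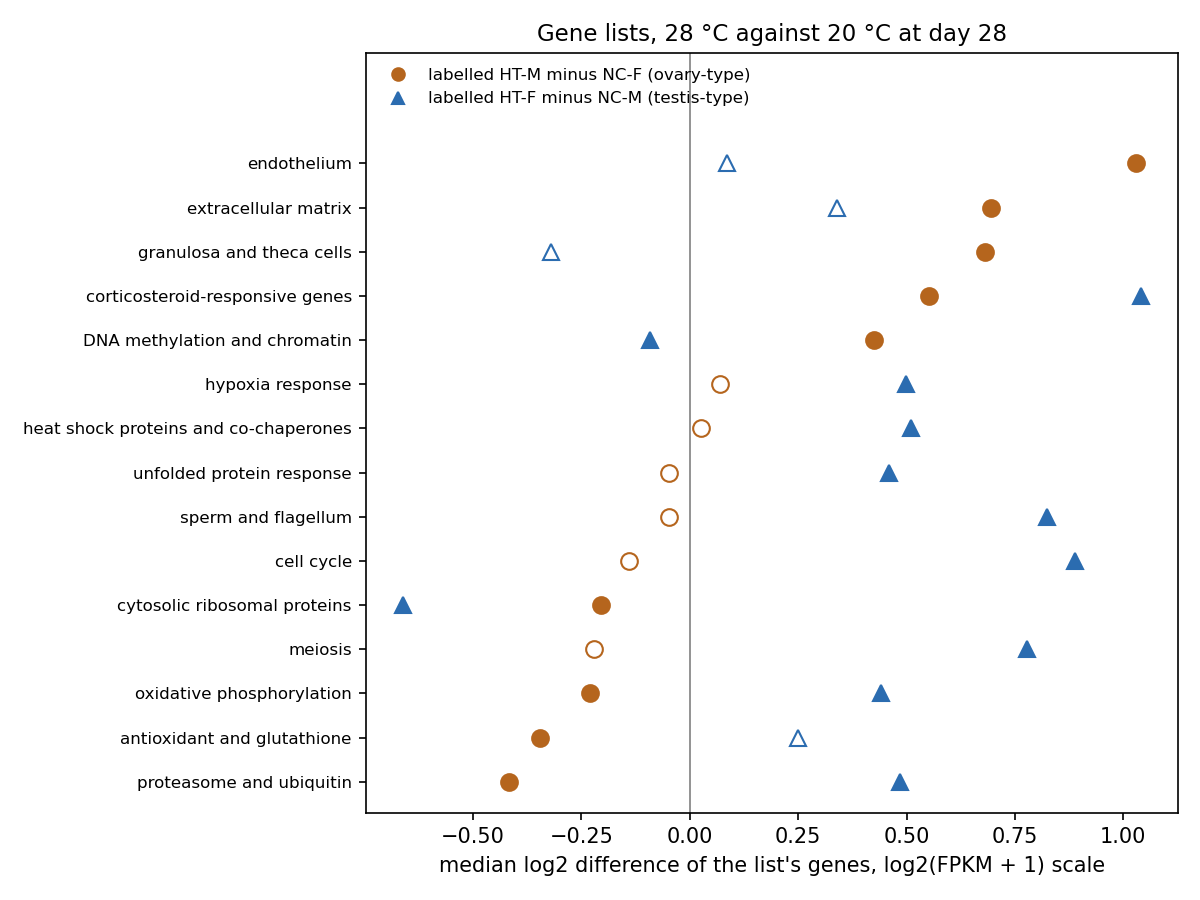
Median log2 difference (28 °C minus 20 °C at day 28) of the 15 lists called by camera in HT-M against NC-F (circles) or HT-F against NC-M (triangles), with filled symbols for lists called in that contrast. Stroma, vessel and corticosteroid lists lay to the right in HT-M against NC-F, while the medians of the heat shock, unfolded protein response and sperm lists in HT-M against NC-F and of the chromatin list in HT-F against NC-M change sign with the scaling.

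The libraries labelled HT-F and NC-M, both testis-type and both from day 28, were compared after the gonad genes had been seen. Transcripts of the mitochondrial genome were lower in HT-F than in NC-M and IC-F. COX1 stood at 2467 ± 546 in HT-F, 28382 ± 1867 in NC-M and 14948 ± 1445 in IC-F (log2 −3.54 ± 0.254 SE, limma adjusted p = 0.000649 for HT-F against NC-M), and COX2 at 1190.3 ± 331, 36188 ± 2161 and 21496 ± 2975 (log2 −4.96 ± 0.286 SE, limma adjusted p = 0.000171). All 12 protein genes of the mitochondrial genome other than ND1 fell, by log2 −4.96 to −2.53 against NC-M and by −4.21 to −1.81 against IC-F. Their share of the FPKM sum, ND1 included, was 1.48% to 2.05% in HT-F, 12.8% to 17.9% in NC-M and 8.38% to 10.1% in IC-F. ND1 was listed at 0 in all 3 libraries labelled HT-F, at 0, 0 and 709 in the 3 libraries labelled NC-M and at 321 ± 97.4 in IC-F. The falls were called in 11 or 12 of the 12 genes under each scaling, under the replicate block and with any library left out.

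Several members of the corticosteroid-responsive list stood higher in HT-F than in NC-M. Dusp1 reached 64.5 ± 32.2 in HT-F against 4.11 ± 2.39 in NC-M (log2 3.61 ± 0.457 SE, limma adjusted p = 0.00979). Ddit4 reached 189.6 ± 97.0 in HT-F against 25.4 ± 22.6 in NC-M (log2 3.01 ± 0.596 SE, limma adjusted p = 0.0293). Klf9, a target of the glucocorticoid receptor, reached 20.1 ± 10.4 in HT-F against 3.43 ± 1.30 in NC-M (log2 2.14 ± 0.402 SE, limma adjusted p = 0.0266). Outside that list, igfbp1a reached 11.4, 68.7 and 69.8 in the 3 libraries labelled HT-F against 1.12 ± 1.17 in NC-M (log2 4.35 ± 0.668 SE, limma adjusted p = 0.0173). Crema, a cAMP-responsive regulator, reached 53.6 ± 19.5 in HT-F against 4.92 ± 1.74 in NC-M (log2 3.17 ± 0.324 SE, limma adjusted p = 0.00512). The clock gene bhlhe40 reached 57.7 ± 36.6 in HT-F against 5.59 ± 2.29 in NC-M, and the lipase gene lipg 52.0 ± 11.5 in HT-F against 12.0 ± 2.27 in NC-M (log2 2.02 ± 0.2 SE, limma adjusted p = 0.00458). Of the 15 corticosteroid-responsive genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone). Their median was log2 1.04 (camera adjusted p = 0.000495, and 0.611 with an estimated correlation). Of the 24 hypoxia response genes, 4 rose and 1 fell (10 and 1 adjusted over the list alone). Their median was log2 0.50 (camera adjusted p = 0.00541, and 0.611 with an estimated correlation). Of the 41 heat shock protein and co-chaperone genes, 8 rose and 0 fell (11 and 0 adjusted over the list alone). Their median was log2 0.51 (camera adjusted p = 0.00197, and 0.611 with an estimated correlation). Of these, the Hsp90 co-chaperone genes stip1 and fkbp4 stood at 47.0 ± 3.88 in HT-F against 27.8 ± 4.04 in NC-M and 75.4 ± 5.55 in HT-F against 48.0 ± 6.61 in NC-M. Of the 39 unfolded protein response genes, 5 rose and 1 fell (9 and 1 adjusted over the list alone). Their median was log2 0.46 (camera adjusted p = 0.00541, and 0.611 with an estimated correlation). In HT-F against IC-F neither this nor the heat shock list was called (medians log2 0.04 and 0.20, and −0.115 and 0.03 after median-of-ratios scaling). Cirbpb stood at 2145 ± 118 in HT-F against 1157 ± 57.1 in NC-M (log2 0.89 ± 0.147 SE, limma adjusted p = 0.0207). The catalase gene cat stood at 122 ± 17.5 in HT-F against 50.3 ± 12.6 in NC-M. Dmrt1 stood at 99.4 ± 16.3 in HT-F against 58.5 ± 4.42 in NC-M, and insl3 at 106 ± 29.5 in HT-F against 42.6, 40.8 and 66.5 in the 3 libraries labelled NC-M. Each of these named genes except crema and lipg lost its call when at least 1 of the 6 libraries was left out.

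Other lists were also called in HT-F against NC-M, and some of the calls depended on single NC-M libraries. The median sperm gene stood at 3.46 and 3.56 in NC-M 1 and NC-M 2, against 5.18 in NC-M 3. Of the 54 nuclear oxidative phosphorylation genes, 6 rose and 0 fell (16 and 0 adjusted over the list alone). The median nuclear oxidative phosphorylation gene changed by log2 0.44 (camera adjusted p = 7.58e-06, and adjusted p = 0.611 with an estimated correlation). Of the 52 proteasome and ubiquitin genes, 4 rose and 0 fell (0 and 0 adjusted over the list alone). The median proteasome and ubiquitin gene changed by log2 0.48 (camera adjusted p = 0.000161, and adjusted p = 0.634 with an estimated correlation). Of the 66 sperm and flagellum genes, 2 rose and 1 fell (0 and 0 adjusted over the list alone). For the sperm and flagellum list the median was log2 0.82 (camera adjusted p = 0.00121, and adjusted p = 0.656 with an estimated correlation). Of the 24 meiosis genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone). The median meiosis gene changed by log2 0.78 (camera adjusted p = 0.0108, and adjusted p = 0.656 with an estimated correlation). Of the 77 cell cycle genes, 2 rose and 1 fell (34 and 1 adjusted over the list alone). For the cell cycle list the median was log2 0.89 (camera adjusted p = 1.69e-06, and adjusted p = 0.634 with an estimated correlation). Of the 88 cytosolic ribosomal protein genes, 0 rose and 4 fell (0 and 0 adjusted over the list alone). For the cytosolic ribosomal protein list the median was log2 −0.66 (camera adjusted p = 5.71e-13, and adjusted p = 0.611 with an estimated correlation). The called members of the ribosomal list include rps6kal and rps6kc1, which are kinases and not ribosomal proteins, beside rps14 at 1178 ± 291 in HT-F against 3610.0 ± 1472 in NC-M. The meiosis call ended without NC-M 1 or NC-M 2, and the sperm call without NC-M 2. With both left out, NC-M 3 alone stood for NC-M and the other groups supplied the spread, so that setting describes 1 library. There the cell cycle, ribosomal, proteasome and unfolded protein response calls ended, and the cell cycle, meiosis and sperm lists turned direction. Of the 63 chromatin and DNA methylation genes, 1 rose and 14 fell (4 and 14 adjusted over the list alone). For the chromatin and DNA methylation list the median was log2 −0.09 (camera adjusted p = 0.023, and adjusted p = 0.611 with an estimated correlation). That call and the hypoxia call ended without NC-M 3, and the chromatin median turned to 0.17 with each library rescaled to a common sum. Suz12b, a Polycomb gene, stood at 16.6 ± 0.982 in HT-F against 49.7 ± 10.8 in NC-M. The deacetylase gene sirt1 stood at 55.4 ± 7.05 in HT-F against 139 ± 30.2 in NC-M, and the leukocyte gene ptprc at 8.33 ± 1.89 in HT-F against 20.7 ± 5.53 in NC-M. Lhcgr stood at 2.15 ± 0.208 in HT-F against 11.9 ± 6.25 in NC-M (log2 −1.93 ± 0.295 SE, limma adjusted p = 0.0171), lower in HT-F than in NC-M.

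Over all 22791 genes tested in HT-F against NC-M, 1407 rose and 1025 fell. The count of 2432 became 1308, 71 and 62 without HT-F 1, HT-F 2 and HT-F 3, 647, 324 and 10693 without NC-M 1, NC-M 2 and NC-M 3, and 851 without both NC-M 1 and NC-M 2, which leaves 1 NC-M library. The majority turned without HT-F 2 (24 rose and 47 fell), HT-F 3 (22 and 40) or NC-M 1 (287 and 360). The count became 29 (9 rose and 20 fell) in a fit of the 6 libraries alone, 129 (62 and 67) with replicate numbers as a block, and 1141 with no filter. Of its called genes, 57.9% rose, against 46.6% after median-of-ratios scaling and 82.9% when each library was rescaled to a common sum. The lists not called, with the counts that rose and fell over all genes and then adjusted over the list alone, were cold-inducible RNA-binding proteins (1 and 0 of 4, then 2 and 0), steroidogenesis (0 and 0 of 13, then 0 and 0), gonadotropin and sex steroid receptors (1 and 2 of 15, then 1 and 5), cholesterol synthesis (3 and 0 of 18, then 3 and 0), oocyte (1 and 2 of 12, then 2 and 2), granulosa and theca cells (0 and 1 of 11, then 0 and 1), Sertoli and Leydig cells (3 and 0 of 15, then 3 and 0), spermatogonia (3 and 1 of 32, then 6 and 2), p53 response (7 and 0 of 34, then 11 and 1), antioxidant and glutathione (3 and 0 of 44, then 2 and 0), glycolysis (1 and 0 of 26, then 0 and 0). The others were fatty acid and lipid metabolism (3 and 1 of 52, then 3 and 1), myeloid cells (2 and 3 of 17, then 2 and 5), lymphocytes (0 and 0 of 6, then 0 and 0), interferon response (1 and 2 of 23, then 1 and 2), complement and acute phase (1 and 0 of 7, then 1 and 0), extracellular matrix (4 and 2 of 49, then 8 and 3), endothelium (2 and 1 of 22, then 5 and 2), red blood cells (1 and 0 of 11, then 1 and 0), liver and yolk precursors (0 and 0 of 5, then 0 and 0), skeletal muscle (0 and 1 of 13, then 2 and 3), circadian clock (4 and 1 of 26, then 6 and 1) and gonadal sex determination (1 and 2 of 18, then 1 and 2).

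**Figure D3:**
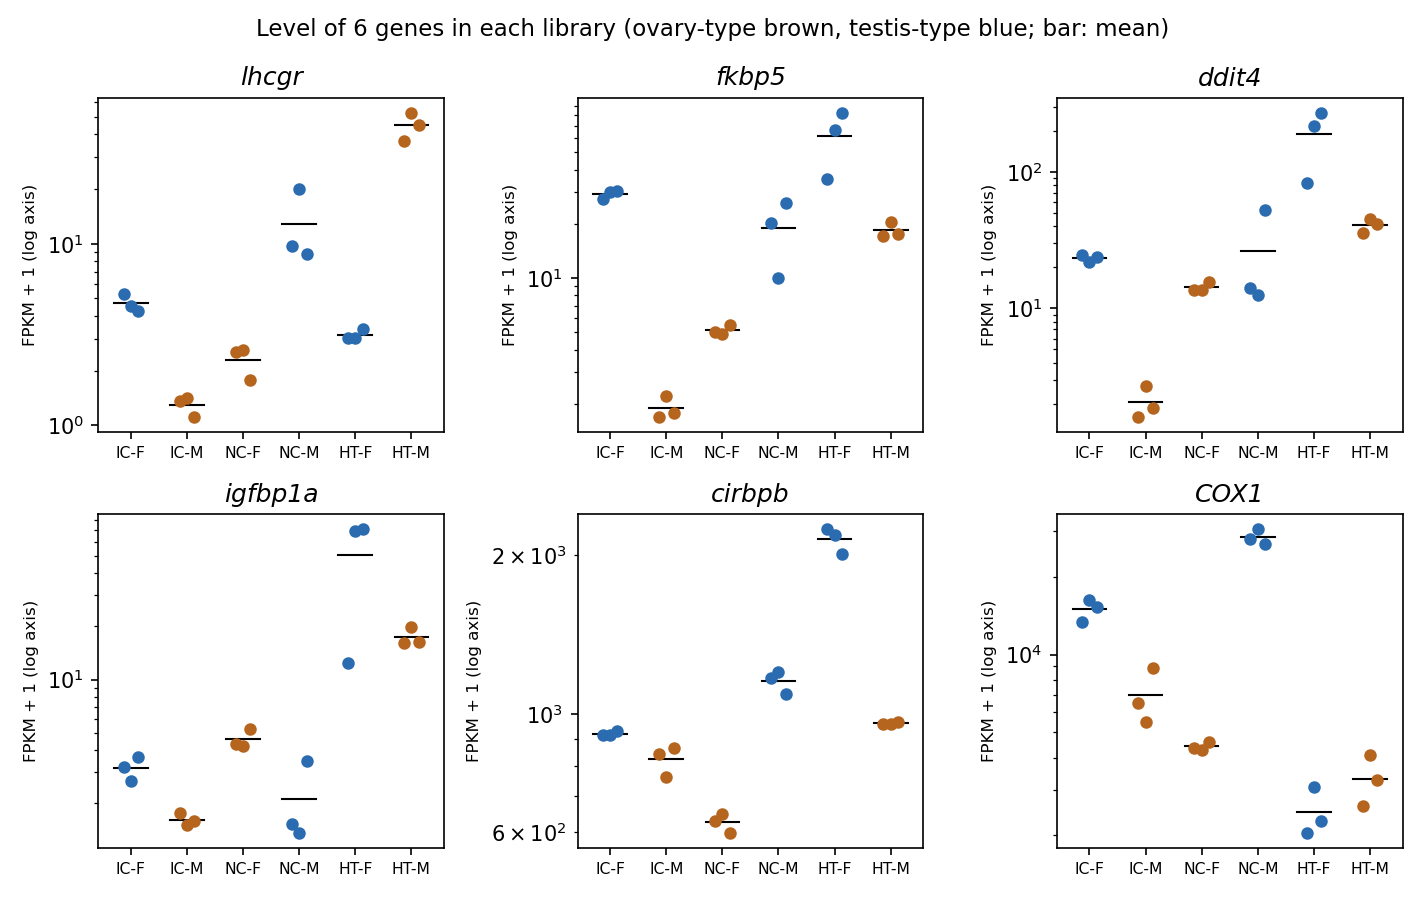
FPKM + 1 of 6 genes in each library (points, brown for ovary-type and blue for testis-type libraries), with the mean of each labelled group of 3 (bar), on a log axis. Lhcgr was highest in HT-M and igfbp1a and ddit4 in HT-F, while COX1 was lower in HT-F than in the other testis-type groups, NC-M and IC-F.

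The same labelled groups were compared between day 0 and day 28 at 20 °C, again after the gonad genes had been seen. In the ovary-type pair, NC-F against IC-M, many of the largest changes were again of genes near 0 in a whole group. Arhgap39 stood at 25.2 ± 1.69 in NC-F against 0.327 ± 0.12 in IC-M, and fgf2 at 19.6 ± 1.66 in NC-F against 0.36 ± 0.05 in IC-M. Nek10 stood at 17.2 ± 2.91 in NC-F against 0.24 ± 0.173 in IC-M, and snx6 at 14.3 ± 1.80 in NC-F against 0.74 ± 0.678 in IC-M. Birc5b stood at 2.61 ± 0.946 in NC-F against 1145 ± 205 in IC-M, and tmprss2 at 0.0733 ± 0.0503 in NC-F against 37.5 ± 5.95 in IC-M. Rab11fip5a stood at 1.42 ± 0.105 in NC-F against 48.5 ± 2.32 in IC-M. Of the 87 cytosolic ribosomal protein genes, 37 rose and 0 fell (46 and 0 adjusted over the list alone). The median cytosolic ribosomal protein gene changed by log2 0.24 (camera adjusted p = 1.21e-07, and adjusted p = 0.51 with an estimated correlation). Of the 10 myeloid cell genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone). For the myeloid cell list the median was log2 0.61 (camera adjusted p = 0.00785, and adjusted p = 0.413 with an estimated correlation). Of the 50 proteasome and ubiquitin genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone). For the proteasome and ubiquitin list the median was log2 0.35 (camera adjusted p = 0.000975, and adjusted p = 0.595 with an estimated correlation). Of the 53 chromatin and DNA methylation genes, 1 rose and 20 fell (1 and 21 adjusted over the list alone). The median chromatin and DNA methylation gene changed by log2 −0.23 (camera adjusted p = 0.000975, and adjusted p = 0.413 with an estimated correlation). The antioxidant, oxidative phosphorylation, glycolysis, endothelium and hypoxia lists rose as well (camera adjusted p between 0.000975 and 0.0372, and adjusted p = 0.595 with an estimated correlation for each), the glycolysis call ending without IC-M 3. The oxidative phosphorylation list holds nuclear genes, and of 12 protein genes of the mitochondrial genome other than ND1, 0 rose and 9 fell. In all, 2034 genes rose and 2311 fell of 17026, and 2340 rose and 2276 fell after median-of-ratios scaling. The count of 4345 became 2432, 2749, 2262 and 2888 without NC-F 1, NC-F 2, NC-F 3 and IC-M 1, and 2815 with all 18 libraries in the fit.

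In the testis-type pair, NC-M against IC-F, sperm genes were lower after 28 days at 20 °C. Of the 66 sperm and flagellum genes, 1 rose and 48 fell (2 and 52 adjusted over the list alone). The median sperm and flagellum gene changed by log2 −1.55 (camera adjusted p = 1.71e-12, and adjusted p = 0.837 with an estimated correlation). This call held with any library left out. The size of the fall rested on NC-M 1 and NC-M 2, whose median sperm gene stood at 3.46 and 3.56, against 5.18 in NC-M 3 and 5.83 to 5.91 in IC-F. The cyclin gene ccnb2 stood at 75.2 ± 107 in NC-M against 519.5 ± 16.1 in IC-F, opn8c at 5.44 ± 7.56 in NC-M against 57.9 ± 1.79 in IC-F. Palm1a stood at 5.93 ± 4.01 in NC-M against 149 ± 7.47 in IC-F, and tgm8 at 158 ± 40.9 in NC-M against 3.21 ± 0.987 in IC-F (log2 5.23 ± 0.283 SE, limma adjusted p = 8.23e-05). Ccnt1 stood at 19.1 ± 9.92 in NC-M against 0.21 ± 0.114 in IC-F and sdad1 at 12.1 ± 4.84 in NC-M against 0 in all 3 libraries labelled IC-F. Odad4 stood at 0, 0 and 45.1 in the 3 libraries labelled NC-M against 117 ± 1.65 in IC-F, and hsf5 at 30.3 ± 50.8 in NC-M against 141 ± 5.66 in IC-F. Ldhba stood at 49.9 ± 15.8 in NC-M against 0.823 ± 0.511 in IC-F, and plekhg2 at 270.0 ± 177 in NC-M against 24.5 ± 9.25 in IC-F. These last 4 genes each lost the call without any 1 of several libraries. Of the 44 antioxidant and glutathione genes, 15 rose and 2 fell (17 and 2 adjusted over the list alone). The median antioxidant and glutathione gene changed by log2 0.50 (camera adjusted p = 0.0051, and adjusted p = 0.837 with an estimated correlation). Of the 23 interferon response genes, 12 rose and 1 fell (16 and 1 adjusted over the list alone). The median interferon response gene changed by log2 0.55 (camera adjusted p = 0.0051, and adjusted p = 0.837 with an estimated correlation). Of the 88 cytosolic ribosomal protein genes, 33 rose and 0 fell (58 and 0 adjusted over the list alone). For the cytosolic ribosomal protein list the median was log2 0.82 (camera adjusted p = 4.75e-09, and adjusted p = 0.837 with an estimated correlation). Of the 39 unfolded protein response genes, 1 rose and 13 fell (2 and 13 adjusted over the list alone). For the unfolded protein response list the median was log2 −0.34 (camera adjusted p = 0.0219, and adjusted p = 0.837 with an estimated correlation). Of the 77 cell cycle genes, 9 rose and 27 fell (10 and 31 adjusted over the list alone). The median cell cycle gene changed by log2 −0.44 (camera adjusted p = 0.0383, and adjusted p = 0.859 with an estimated correlation). The unfolded protein response call ended without NC-M 1, and the cell cycle call without NC-M 1 or NC-M 2. With both left out, which leaves 1 NC-M library, the ribosomal call ended as well. Of 12 protein genes of the mitochondrial genome other than ND1, 5 rose, and 2, 3 and 9 did so without NC-M 2, IC-F 2 and NC-M 3, while no such call was left without IC-F 1 or IC-F 3, and 2 were left with each library rescaled to a common sum. In all, 3736 genes rose and 4133 fell of 22791, a majority that turned without NC-M 1 (3101 and 3100) or NC-M 3 (6155 and 5994) and with all 18 libraries in the fit (5791 and 5377). The count of 7869 became 4985 and 12149 without NC-M 2 and NC-M 3, and 4121, 3787 and 3797 without IC-F 1, IC-F 2 and IC-F 3.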

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

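The tests of the label pattern and the counts of splits were chosen only after the results were seen, as were all contrasts between groups of like gonads. The heat effects of the groups differed in a test of the difference itself for the results that follow. For the planned difference, (HT-F minus NC-F) minus (HT-M minus NC-M), 21143 genes were called. The log2 differences were 17.25 for gabrd, 16.53 for stmn1b, 16.52 for odf3b, 15.65 for si_dkey-91i10.3 and 15.61 for rsph1, and −18.24 for zpcx, −18.01 for tlr18, −17.94 for map1lc3c, −17.79 for zar1l and −17.75 for btg4 (limma adjusted p between 9.7e-18 and 3.71e-14). Odf3b and rsph1 are in the sperm and flagellum list and zar1l and btg4 in the oocyte list, and the contrast sums differences between testis-type and ovary-type libraries.

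The letters went against the gonad genes in 12 of 12 IC and HT libraries. An exchange of F and M there, or a matching one of prefixes, may account for it, since each group had its partner in the other letter. Tissue of both gonads in each library is argued against, since the median of 16 oocyte genes stood in testis-type libraries at 0.924% of its level in ovary-type libraries, and the median of 58 sperm genes at 0.787% the other way round. A change of gonad type under heat alone is argued against. The 12 libraries include 6 labelled as day 0, and only 6 were heated, whichever prefixes are right. For the HT libraries a change under heat stays open. All 6 had the gonad type of the IC libraries of the same letter, which counts against it only if the IC labels are right, and these are in doubt. Which labels are right stays open, and with it whether each contrast of like gonads holds the temperature and the day that its prefixes name.

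For the difference between the heat effects of like gonads, (HT-M minus NC-F) minus (HT-F minus NC-M), 8221 genes were called, and 12914 without NC-M 3. Lhcgr differed by log2 6.22 (SE 0.365, limma adjusted p = 4.22e-08), rising in ovary-type and falling in testis-type libraries. Its rise may depend on how reads were assigned, since an unnamed entry stood at 31.6 to 82.9 in ovary-type libraries with lhcgr at 1 FPKM or less and at 0 where it was on, but the entry mirrored hspb9 and igfbp1a too, and this stays open. Kdm6bb differed by 2.41 and stip1 by −1.23, each moving in opposite directions in the 2 gonad types. Igfbp1a (−2.43), dusp1 (−2.36) and bhlhe40 (−1.73) rose in both and more in the testis-type libraries. Birc5b (8.98), plekhg2 (5.40), tmem41aa (5.19), mrm3a (5.15), mettl3 (−7.81), mrps15 (−6.05), nek10 (−4.74), acat2 (−4.55) and myl2b (−4.46) also differed, and most of them are among the genes listed near 0 in whole groups.

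Other splits of the same libraries were counted for each contrast, with libraries exchanged within each pair of groups compared. For the planned difference of heat effects, 1 of 100 drawn splits gave as many calls, the real one, with 14837 as the highest other. For the difference of like gonads it was also 1 of 100, with 7094 as the highest other. The other splits of the planned difference mix unlike gonads within a group, which widens the spread, so their lower counts decide nothing. For like gonads the real count was the highest of those drawn, but these splits do not test how far the 2 heat effects differ. Without NC-F 3 the count of 8221 became 6212, under the 7094 of another split, so chance is not excluded. The cause of the high counts of other splits was not tested. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. There the real counts and the highest of the other splits were 19005 and 1 for HT-F against NC-F, 15709 and 1 for HT-M against NC-M, 19464 and 0 for NC-F against IC-F, 16017 and 1 for NC-M against IC-M, 11913 and 6 for HT-F against IC-F, 1756 and 8 for HT-M against IC-M, and 19620 and 2 for IC-F against IC-M. For the like gonads they were 8299 and 2 for HT-M against NC-F, 2432 and 40 for HT-F against NC-M, 4345 and 1 for NC-F against IC-M, and 7869 and 2 for NC-M against IC-F. For the gene lists, 6, 4, 5 and 4 of the 10 splits gave as many called lists as HT-F against NC-F (5 lists, highest other 12), HT-M against NC-M (8 and 11), NC-F against IC-F (7 and 10) and NC-M against IC-M (10 and 10). They were 3, 1, 1 and 5 of 10 for HT-M against NC-F (9 and 10), HT-F against NC-M (11 and 10), NC-F against IC-M (9 and 8) and NC-M against IC-F (6 and 10).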

How the results depend on the processing

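All results on groups of like gonads, the fits of 1 gonad type and the fits without NC-M 1 and NC-M 2 were chosen only after the data were seen. Of 5281 values of 350 results on named genes under other settings, 4541 kept direction and call, 734 kept direction and lost the call (643 of them in HT-F against NC-M), 6 gained it and 0 changed direction. Of the 98 named genes of HT-F against NC-M, 14 kept their call with any library left out, and 108 of 109 did in HT-M against NC-F. Depth is unknown, so what depth limits could not be measured. The cause of the differences below was not tested except where fewer genes or libraries enter by construction.

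With an added log2 threshold of 1, the counts were 3896 for HT-F against IC-F, 2616 for HT-M against NC-F, 1279 for HT-F against NC-M, 1223 for NC-F against IC-M, 4490 for NC-M against IC-F and 5410 for the difference of like gonads. A filter at 5 FPKM tested fewer genes and gave 10354 for HT-M against NC-M and 10496 for NC-M against IC-M. With all 18 libraries in the fit, the counts were 3080 for HT-M against IC-M, 8568 for HT-F against NC-M and 2815 for NC-F against IC-M, and with the 6 libraries alone 3235 for HT-M against IC-M and 29 for HT-F against NC-M. Fits of 1 gonad type gave 5438 for HT-F against IC-F and 4179 for HT-M against IC-M. HT-F against NC-M gave 1141 with no filter, 4980 rescaled to a common sum, and 851 without NC-M 1 and NC-M 2 (1 NC-M library left), 435 of them among the 2432.

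The replicate numbers share only a number: same-numbered libraries of different groups correlated in their deviations at −0.243 to 0.242 over the 4 fits. With the numbers as a replicate block, HT-F against NC-M had 129 calls in place of 2432, and no other count moved by over 1.5 times.

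With an estimated correlation, camera called 0 lists for HT-F against NC-F, 1 for HT-M against NC-M, 0 for NC-F against IC-F, 1 for NC-M against IC-M and 0 for each of the 4 contrasts of like gonads at day 28 or at 20 °C. Median-of-ratios scaling gave 12 lists in place of 5 for HT-F against NC-F. Against the values as deposited, the median of all genes shifted by −0.393 to 0.266 after median-of-ratios scaling (−0.0444 in HT-M against NC-F and −0.0604 in HT-F against NC-M) and by −0.185 to 0.302 after rescaling (0.119 and 0.236). The share of higher calls moved by over 10 points after median-of-ratios scaling in 6 contrasts, among them the fits of 1 gonad type of HT-M against IC-M (65.6% to 54.1%) and HT-F against IC-F (62.1% to 44.7%), and after rescaling in 3, among them the latter (to 73.6%).

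Leaving out each library in turn gave 17036 to 18894 calls for HT-F against NC-F, 11072 to 14669 for HT-M against NC-M, 17619 to 18252 for NC-F against IC-F, 11454 to 15285 for NC-M against IC-M, 9427 to 13188 for HT-F against IC-F, 805 to 1505 for HT-M against IC-M, 20557 to 21218 for the planned difference and 18379 to 18832 for IC-F against IC-M. For like gonads it gave 6242 to 7507 for HT-M against NC-F, 62 to 10693 for HT-F against NC-M, 2262 to 4393 for NC-F against IC-M, 3787 to 12149 for NC-M against IC-F and 6212 to 12914 for their difference. The libraries that moved a count by over 1.5 times are named with each count in the report, and the last range had its highest value without NC-M 3. The lists called numbered 3 to 10, 6 to 9, 6 to 9 and 8 to 10 in the planned HT-F against NC-F, HT-M against NC-M, NC-F against IC-F and NC-M against IC-M. For like gonads they numbered 9 to 10 in HT-M against NC-F, 9 to 15 in HT-F against NC-M, 8 to 9 in NC-F against IC-M, 4 to 9 in NC-M against IC-F, 6 to 10 in HT-M against IC-M and 9 to 11 in HT-F against IC-F.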

Other observations

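The test of ovary RNA, that of libraries from 1 fish and all comparisons of like gonads were chosen only after results were seen. At day 28, the heat effects of the 2 gonad types were not correlated positively across genes. Across 14835 genes tested in both, the log2 changes of HT-M against NC-F and HT-F against NC-M had a Pearson correlation of −0.0753 (Spearman −0.102; genes are not independent replicates). In both, 347 genes rose, where lists independent of each other would share 354.7, and 66 fell, where they would share 107. Genes that rose in ovary-type and fell in testis-type libraries numbered 201 (158.2 for independent lists, Fisher p = 6.11e-05), and the reverse 271 (240.0, p = 0.0217). Ddit4 and cirbpb rose in both, as did the corticosteroid list (adjusted p = 0.43 and 0.611 with an estimated correlation). Against day 0, 576 genes rose in both gonad types, where independent lists would share 454.2 (odds ratio 1.44, Fisher p = 1.39e-11), and 89 fell, where they would share 72.2. Within a gonad type, the changes against NC and against IC share the HT libraries. In ovary-type libraries 1988 genes rose and 887 fell against both, with 786.9 and 288.1 for independent lists, and in testis-type libraries 619 and 199, with 208.5 and 92.7. In 20 simulations of unchanged groups on shared libraries, the mean numbers shared were 0 and 0.05 for rises. Almost no gene is called in unchanged groups, so these numbers do not measure the overlap that shared libraries bring where many genes are called. The covariance of the changes was 0.429 in ovary-type libraries (0.0436 simulated) and 0.22 in testis-type libraries (0.091 simulated). The simulated correlations, from shared libraries alone, were 0.507 and 0.5 beside 0.615 and 0.307 observed. In testis-type libraries the observed correlation was thus below the simulated one. How much of the overlap comes from the shared libraries stays open in both gonad types. The overlaps between gonad types at day 28 use the 2432 calls of HT-F against NC-M, which became 1308, 71 and 62 without HT-F 1, HT-F 2 and HT-F 3, and 647, 324 and 10693 without NC-M 1, NC-M 2 and NC-M 3.

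Sperm genes were lower in NC-M 1 and NC-M 2 than in NC-M 3, by a median of 1.69 log2. A few abundant transcripts taking the reads are argued against, since the gap was 1.66 after median-of-ratios scaling (spread 0.158). Ovary RNA is argued against too, with the median oocyte gene at 0.839% and 0.355% of its NC-F level in these libraries and 1.06% in NC-M 3. A smaller share of germ cells could account for the gap: the lists of endothelium, extracellular matrix, myeloid cells and Sertoli and Leydig cells had median differences from 0.201 (spread 0.201, endothelium) to 0.63, and since the lowest is within its spread and the bound was tightened after the value was seen, this stays open. A biological difference between fish, such as the stage of the testis, was not tested.

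Within a gonad type, 155 genes in ovary-type and 181 in testis-type libraries, 25 of them in both, were on (5 FPKM or more) in some libraries and off (0.5 or less) in the others. Reads assigned to a neighbouring annotated gene are argued against, since 4.72% of 254 such genes had an adjacent gene that was higher where they were off, and 4.7% of random genes did. Reads assigned to an unnamed transcript of the table may account for part of them: 39.8% of 256 had an MSTRG entry with the complementary values, against 9.36% with shuffled libraries, but the shuffling breaks up the groups, 1 entry matched ND1, mettl3, rhbdd1 and myl2b alike, and the test was added after that on neighbours. Libraries of a group made from 1 fish or 1 pool, with alleles that map or not, could also do so, and the share of such genes alike in all 3 libraries ran from 29.8% in NC-M to 81.3% in NC-F, which decides nothing where estimates fail at random. A biological change stays open, since no test of it was made.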
